A study of Rattus norvegicus and Mus musculus with 61 samples.

How the data were processed

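Expression arrays measured total RNA from parieto-occipital cortex of male mice and rats after experimental brain injury. Mouse samples were 4 mm disks pooled from 3 animals, taken 4, 8, 24 or 72 h after a controlled cortical impact (6 m/s, 1.5 mm deformation) or sham surgery, or from naive mice. Rat samples were 7 mm disks from 1 animal each, taken 30 min, 4, 8, 24 or 72 h or 21 d after fluid percussion (2.5 atm) or sham surgery, or from naive rats. Groups were read from the sample labels alone: 22 mouse arrays (12 injury, 8 sham, 2 naive) and 39 rat arrays (20 injury, 16 sham, 3 naive) in 22 groups. Mouse sham titles of a time share the number 1 and differ in a letter (1b and 1c, or 1c and 1d), while injury samples are numbered 1 to 3. The sham arrays were taken as separate samples, which the labels leave open, and p-values measure the spread between arrays.

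The deposited values were 1 intensity per probe set and array on a linear scale, for 12488 mouse and 8799 rat probe sets. The software that made the deposited intensities is not stated in the labels or file headers used here. The values themselves showed a common scale: the mean after trimming 2% at each end was 800.3 to 800.5 in mouse and 800.6 to 801.2 in rat. The median deposited signal was 285 to 340 in mouse and 230 to 409 in rat.

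Intensities were kept on the deposited scale, floored at the pooled 10th percentile (24.1 in mouse, 32.1 in rat) and taken as log2. Control probe sets (66 in mouse, 59 in rat) were left out. Probe sets above the pooled 40th percentile (194 in mouse, 202 in rat) in at least 3 arrays passed the filter, 8477 in mouse and 7162 in rat. Probe sets with 1 gene symbol were kept, and a gene with several was represented by the one with the highest mean, which left 6355 mouse and 4091 rat genes. A fold change against a group whose arrays all sat at the floor is a lower bound and is written "at least".

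Each species had 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 with moderated variances and a mean trend (13 residual degrees of freedom in mouse, 26 in rat). Contrasts were injury against time-matched sham, the mean of the sham groups against naive, and the difference of the injury effects at 72 h and 4 h. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Values in the text are log2 differences ± the standard error from limma. In 26 gene lists fixed before the data were examined, camera in limma was run with a preset correlation of 0.01 between genes, and adjusted over lists and contrasts within a species. It was run again with the correlation estimated from each list's residuals, and fry was the other list test. Lists with fewer than 4 measured genes were not tested. Mouse and rat changes were compared by gene symbol with Pearson and Spearman correlations and Fisher's exact test.

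Named genes followed a rule fixed before the data were examined. It took, for each injury contrast, the 6 largest rises and 6 largest falls among called genes with at least a 2-fold change and every injury array on the same side of every time-matched sham array. It added up to 3 called members per list with the smallest adjusted p, 4 rises and 4 falls for the other contrasts, and up to 8 genes per time called in both species. The text prints some of these, mainly those that best kept their calls.

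The fit was tested on simulated data with known changes placed among the real array spreads. For mouse 72 h, 93.9% of 4-fold and 53.7% of 2-fold changes were recovered, against 68.2% and 23.9% for rat 4 h, 54.5% and 4.48% for rat 8 h, and 50% and 5.97% for rat 24 h. Alternatives fixed before the data were examined were quantile normalization, no filter, a floor at the 25th percentile, the mean of a gene's probe sets, the title letter as a block, replicate number as a block, only the compared groups in the fit, all uninjured arrays as 1 control group, averaged mouse sham arrays, and leaving out each array in turn. Left-out arrays are named by group and replicate, as in sham 1c. Where an array left out or an average left 1 sham sample, limma assumed that it varied like the other groups. Chosen after the data were seen were a rat fit without 4 arrays, a covariate of antisense control probe sets, and leave-one-out fits of lists and species correlations. Probe sets with several gene symbols (396 in mouse, 308 in rat) or none (1193 and 1426) were not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.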

Results

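The series followed gene expression in injured parieto-occipital cortex over time in mouse and rat. Mouse groups held 3 injury and 2 sham samples at each of 4 times, with 2 naive samples. Rat groups held 5 injury and 4 sham samples at 30 min, 3 and 4 at 4 h, 3 and 2 at later times, with 3 naive samples. Every mouse array had a median correlation of at least 0.889 with the other mouse arrays. In rat, 4 arrays stood apart with medians of 0.498 (sham 4 h replicate 4), 0.633 (sham 4 h replicate 3), 0.729 (injury 30 min replicate 5) and 0.780 (sham 30 min replicate 3). The other rat arrays had 0.809 to 0.924. Rat counts are therefore also given without these 4 arrays, a choice made after seeing the data.

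**Figure D1:**
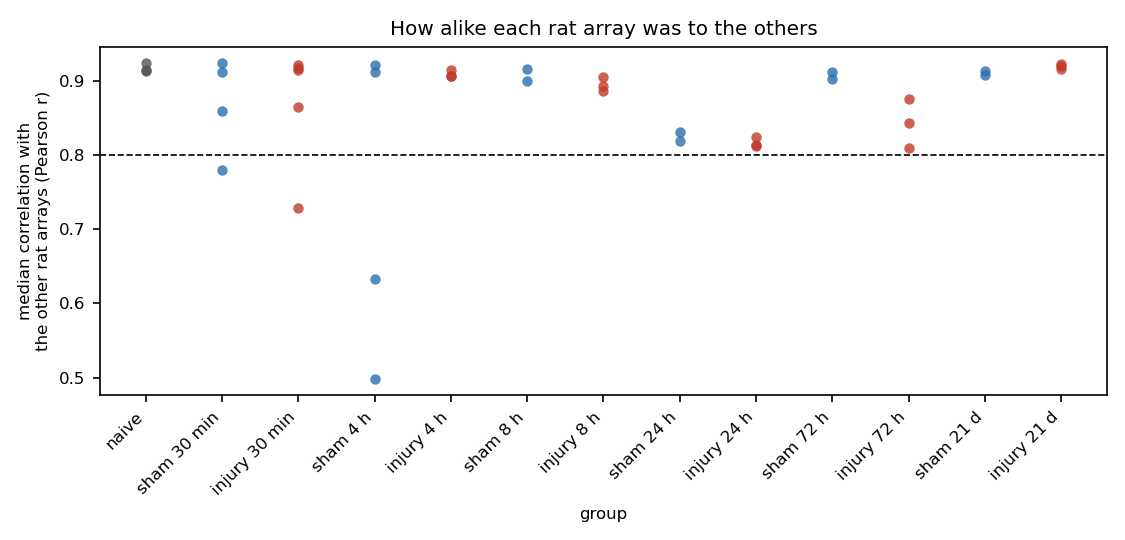
Median Pearson correlation of each rat array (log2 signal) with the other rat arrays, by group. The dashed line marks 0.8, below which 4 of the 39 arrays fell.

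Injury against sham in mouse asked which genes had changed by each time after the impact. At 4 h, the lists of cytokines and chemokines and of immediate early genes were higher in injured cortex. Among rises were the chemokines Ccl3 (2.88 ± 0.34, adjusted p = 6.27e-05) and Ccl12 (2.91 ± 0.47, adjusted p = 0.00231). The urokinase receptor gene Plaur (3.22 ± 0.36, adjusted p = 3.52e-05) and the stress gene Gadd45g (2.38 ± 0.31, adjusted p = 0.000227) also rose. So did the chemokine Ccl4 (3.89 ± 0.64, adjusted p = 0.00241) and the inflammatory cytokine Il1b (3.19 ± 0.52, adjusted p = 0.00212). Some of these calls depended on 1 choice: Ccl12 had adjusted p = 0.051 with averaged sham arrays, Ccl4 had adjusted p = 0.0911 without sham 1b, and Il1b had adjusted p = 0.0606 without sham 1b. Called in total were 55 genes (43 rose, 12 fell, limma with 3 injury and 2 sham arrays).

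Cytokines and chemokines rose as a list in mouse at 4 h (7 of 15 rose, 11 rose and 1 fell adjusted within the list, adjusted p = 1.74e-15, adjusted p = 0.00554 with an estimated correlation). Immediate early genes rose (6 of 24 rose and 1 fell, 14 rose and 1 fell adjusted within the list, adjusted p = 1.92e-14, adjusted p = 0.0224 with an estimated correlation), among them Ier2 (1.57 ± 0.23, adjusted p = 0.00106). Red blood cell markers rose (2 of 4 rose, 2 rose adjusted within the list, adjusted p = 0.000135, adjusted p = 0.0119 with an estimated correlation). Their member Hbb-b2 (1.58 ± 0.24, adjusted p = 0.00122) had adjusted p = 0.0508 without sham 1c. With the preset correlation only, reactive astrocyte markers were higher (3 of 16 rose, 5 rose adjusted within the list, adjusted p = 1.89e-05, adjusted p = 0.069 with an estimated correlation). Cell death and p53 genes were likewise higher (1 of 14 rose, 5 rose adjusted within the list, adjusted p = 0.000141, adjusted p = 0.0552 with an estimated correlation). The same held for adhesion and protease genes (1 of 14 rose, 2 rose adjusted within the list, adjusted p = 0.000336, adjusted p = 0.145 with an estimated correlation). Neuronal genes were lower as a list (0 of 25 called, 0 adjusted within the list, adjusted p = 0.0012, adjusted p = 0.211 with an estimated correlation).

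Heat shock genes in mouse at 4 h were higher (1 of 17 rose, 3 rose adjusted within the list, adjusted p = 0.0219, adjusted p = 0.164 with an estimated correlation). The list had adjusted p = 0.0812 without injury 1 and 0.0809 without sham 1b. Interferon response genes were higher (0 of 10 called, 2 rose adjusted within the list, adjusted p = 0.0166, adjusted p = 0.243 with an estimated correlation). The call had adjusted p = 0.206 without injury 1 and 0.12 without sham 1b. Oxidative phosphorylation genes were lower (0 of 23 called, 1 fell adjusted within the list, adjusted p = 0.0371, adjusted p = 0.312 with an estimated correlation). It had adjusted p = 0.385 without sham 1c, 0.0806 without injury 2, 0.0557 without injury 3, 0.421 after quantile normalization and 0.207 with no filter.

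Some pituitary hormone genes were among the mouse falls at 4 h. Prolactin, Prl (-4.59 ± 0.49, adjusted p = 2.97e-05), and the hormone precursor gene Pomc (-4.16 ± 0.55, adjusted p = 0.00026) fell most. The hormone subunit genes Cga (-4.02 ± 0.42, adjusted p = 2.88e-05) and Lhb (-1.61 ± 0.19, adjusted p = 5.88e-05) fell with Dlk1 (-1.52 ± 0.24, adjusted p = 0.0016). Both sham 4 h arrays stood above all other mouse arrays in these genes: Prl signal was 8270 and 8861 there and at most 459 elsewhere. Against all uninjured arrays as 1 control group, none of these falls was called (Prl adjusted p = 0.796, Pomc 0.814, Cga 0.45, Lhb 0.476, Dlk1 0.561). The count of 55 genes became 27 without injury replicate 1 and 18 without sham replicate 1c. It was 443 against all uninjured arrays and 19 with the sham arrays averaged.

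**Figure D2:**
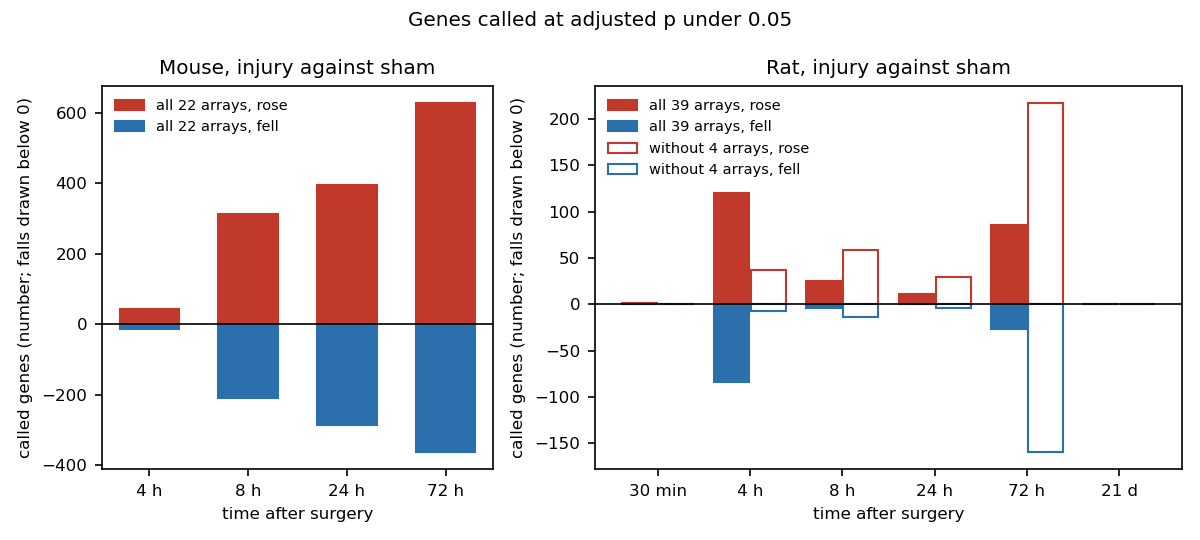
Number of genes called by limma (adjusted p below 0.05) as higher or lower in injury than in time-matched sham, by time, for mouse and rat. Open rat bars leave out the 4 arrays that stood apart, which gave 44 genes in place of 204 at rat 4 h.

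At 8 h in mouse, chemokine genes and markers of reactive astrocytes and of microglia and macrophages were higher. The neutrophil attractant gene Cxcl1 (5.96 ± 0.58, adjusted p = 1.53e-06) and the monocyte attractant gene Ccl2 (5.64 ± 0.38, adjusted p = 1.71e-08) led the rises. The chemokine genes Ccl9 (5.29 ± 0.53, adjusted p = 2.19e-06) and Ccl3 (4.73 ± 0.34, adjusted p = 3.26e-08) followed. The calcium-binding genes of myeloid cells S100a9 (at least 4.71 ± 0.67, adjusted p = 0.000139) and S100a8 (3.95 ± 0.37, adjusted p = 1.21e-06) also rose. Called were 520 genes (312 rose, 208 fell). The count was 194 without sham replicate 1b, 309 with only the compared groups, 781 against all uninjured arrays and 191 with the sham arrays averaged.

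The cytokine list rose in mouse at 8 h (11 of 15 rose, 12 rose adjusted within the list, adjusted p = 2.07e-15, adjusted p = 0.00554 with an estimated correlation). Reactive astrocyte markers rose (11 of 16 rose, 12 rose adjusted within the list, adjusted p = 5.62e-14, adjusted p = 0.00639 with an estimated correlation), with Timp1 (2.92 ± 0.25) and Serpina3n (1.93 ± 0.25). Microglia and macrophage markers rose (6 of 18 rose, 11 rose and 1 fell adjusted within the list, adjusted p = 3.33e-07, adjusted p = 0.026 with an estimated correlation), with Cd14 (2.72 ± 0.24) and Lgals3 (at least 3.63 ± 0.51). Immediate early genes rose (12 of 24 rose, 12 rose adjusted within the list, adjusted p = 1.49e-10, adjusted p = 0.0464 with an estimated correlation), with Zfp36 (2.85 ± 0.35) and Atf3 (2.27 ± 0.28). Cell death and p53 genes rose (6 of 14 rose and 1 fell, 6 rose and 1 fell adjusted within the list, adjusted p = 2.31e-05, adjusted p = 0.0386 with an estimated correlation), with Gadd45b (3.03 ± 0.29) and the cell cycle inhibitor gene Cdkn1a (2.36 ± 0.22). Interferon response genes rose (5 of 10 rose, 6 rose adjusted within the list, adjusted p = 1.11e-05, adjusted p = 0.047 with an estimated correlation), with Gbp2 (3.98 ± 0.35).

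Other rises in mouse at 8 h were the heme oxygenase gene Hmox1 (1.69 ± 0.21, adjusted p = 2.48e-05) and the glucose transporter gene Slc2a1 (1.41 ± 0.19, adjusted p = 7.38e-05). Falls included the splicing factor gene Sf3b1 (-2.65 ± 0.42, adjusted p = 0.000408) and the growth cone gene Gap43 (-0.87 ± 0.17, adjusted p = 0.0026).

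Lists called in mouse at 8 h with the preset correlation only were 7. Complement genes were higher (3 of 10 rose, 7 rose adjusted within the list, adjusted p = 0.000336, adjusted p = 0.069 with an estimated correlation). Oligodendrocyte and myelin markers were higher (3 of 10 rose, 4 rose adjusted within the list, adjusted p = 0.00103, adjusted p = 0.14 with an estimated correlation). Adhesion and protease genes were higher (4 of 14 rose, 6 rose adjusted within the list, adjusted p = 0.00263, adjusted p = 0.229 with an estimated correlation). Antigen presentation genes were higher (3 of 13 rose, 4 rose adjusted within the list, adjusted p = 0.0022, adjusted p = 0.0602 with an estimated correlation). Cholesterol synthesis genes were higher (3 of 13 rose, 3 rose adjusted within the list, adjusted p = 0.0174, adjusted p = 0.174 with an estimated correlation). This list had adjusted p = 0.0659 without sham 1b. Red blood cell markers were higher (2 of 4 rose, 3 rose adjusted within the list, adjusted p = 0.0368, adjusted p = 0.0987 with an estimated correlation). The same list had adjusted p = 0.0561 without injury 2, 0.0516 without sham 1b, 0.0501 without injury 3, 0.0741 without sham 1c and 0.0525 with averaged sham arrays. Oxidative phosphorylation genes were lower (2 of 23 fell, 3 fell adjusted within the list, adjusted p = 0.0254, adjusted p = 0.274 with an estimated correlation). This call had adjusted p = 0.0519 without injury 1, 0.109 without sham 1c and 0.0602 after quantile normalization.

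At 24 h in mouse, reactive astrocyte markers were the list with the smallest p, and 680 genes were called (394 rose, 286 fell). The pentraxin gene Ptx3 (at least 5.95 ± 0.45, adjusted p = 6.52e-08) and the kallikrein protease gene Klk6 (at least 5.71 ± 0.44, adjusted p = 7.33e-08) rose most. The monocyte attractant gene Ccl2 (at least 5.22 ± 0.38, adjusted p = 4.43e-08) and the arginase gene Arg1 (4.47 ± 0.62, adjusted p = 7.90e-05) followed. Falls included the calcium-binding neuronal gene Calb1 (-1.56 ± 0.20, adjusted p = 3.01e-05) and the astrocyte gap junction gene Gja1 (-1.07 ± 0.16, adjusted p = 0.000249). The count was 378 without sham replicate 1c, 249 without sham replicate 1d, 296 with only the compared groups, 1208 against all uninjured arrays and 255 with the sham arrays averaged.

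Reactive astrocyte markers in mouse at 24 h rose (14 of 16 rose, 14 rose adjusted within the list, adjusted p = 4.96e-24, adjusted p = 0.00243 with an estimated correlation), with the intermediate filament gene Nes (2.34 ± 0.17), Serpina3n (2.88 ± 0.25) and Timp1 (2.42 ± 0.25). Microglia and macrophage markers rose (10 of 18 rose, 12 rose adjusted within the list, adjusted p = 3.56e-13, adjusted p = 0.00554 with an estimated correlation), with Lgals3 (at least 4.29 ± 0.51) and Lyz2 (2.50 ± 0.33). Complement genes rose (5 of 10 rose, 5 rose adjusted within the list, adjusted p = 6.80e-05, adjusted p = 0.0497 with an estimated correlation), with C1qb (1.36 ± 0.14), C1qa (1.21 ± 0.20) and C1qc (1.09 ± 0.18). Immediate early genes rose (11 of 24 rose and 1 fell, 15 rose and 1 fell adjusted within the list, adjusted p = 1.20e-10, adjusted p = 0.0464 with an estimated correlation), with Atf3 (2.22 ± 0.28). Cytokines and chemokines rose (8 of 15 rose, 11 rose and 1 fell adjusted within the list, adjusted p = 1.41e-08, adjusted p = 0.026 with an estimated correlation), with Ccl9 (4.37 ± 0.53). Interferon response genes rose (7 of 10 rose, 8 rose adjusted within the list, adjusted p = 1.14e-06, adjusted p = 0.0332 with an estimated correlation), with Gbp2 (3.23 ± 0.35). Oxidative stress genes rose (5 of 19 rose, 5 rose adjusted within the list, adjusted p = 0.00103, adjusted p = 0.0212 with an estimated correlation), with Hmox1 (2.30 ± 0.21). In the inhibitory neuron list 4 of 16 fell and 1 rose, and the list was not called (adjusted p = 0.14 by camera).

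Lists higher in mouse at 24 h with the preset correlation only included adhesion and protease genes (6 of 14 rose, 6 rose adjusted within the list, adjusted p = 6.79e-05, adjusted p = 0.104 with an estimated correlation). Fibroblast and matrix genes were higher (7 of 20 rose, 8 rose and 1 fell adjusted within the list, adjusted p = 0.00293, adjusted p = 0.104 with an estimated correlation). The oligodendrocyte list was higher (4 of 10 rose, 5 rose adjusted within the list, adjusted p = 0.00306, adjusted p = 0.188 with an estimated correlation), with Mag (1.11 ± 0.21). Heat shock genes were higher (3 of 17 rose, 3 rose adjusted within the list, adjusted p = 0.00668, adjusted p = 0.104 with an estimated correlation), with Bag3 (1.53 ± 0.24). Cell death and p53 genes were higher (6 of 14 rose, 6 rose adjusted within the list, adjusted p = 0.000405, adjusted p = 0.069 with an estimated correlation), with Cdkn1a (2.38 ± 0.22). The antigen presentation list was higher (3 of 13 rose, 4 rose adjusted within the list, adjusted p = 0.0103, adjusted p = 0.097 with an estimated correlation). Cholesterol synthesis genes were higher (5 of 13 rose, 6 rose adjusted within the list, adjusted p = 0.000684, adjusted p = 0.069 with an estimated correlation). Endothelial and pericyte markers were higher (4 of 18 rose and 1 fell, 6 rose and 1 fell adjusted within the list, adjusted p = 0.0284, adjusted p = 0.0922 with an estimated correlation). The group had adjusted p = 0.109 without injury 2 and 0.0527 without sham 1c. Cell cycle genes were higher (5 of 22 rose, 5 rose adjusted within the list, adjusted p = 0.00191, adjusted p = 0.0922 with an estimated correlation). That list had adjusted p = 0.0556 without sham 1d.

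At 72 h in mouse, macrophage, complement, matrix and cell cycle genes were higher and 987 genes were called (626 rose, 361 fell). The protease gene Klk6 (at least 6.19 ± 0.44, adjusted p = 1.14e-08) and the macrophage lectin gene Lgals3 (at least 6.08 ± 0.51, adjusted p = 8.51e-08) rose most, with the lysozyme gene Lyz2 (5.37 ± 0.33, adjusted p = 2.67e-09) and Arg1 (at least 5.17 ± 0.62, adjusted p = 1.03e-05). Calbindin, Calb1 (-1.57 ± 0.20, adjusted p = 1.83e-05), fell. The count was 615 without injury replicate 3, 491 without sham replicate 1d, 551 with the title letter as a block, 475 with only the compared groups, 1504 against all uninjured arrays and 469 with the sham arrays averaged.

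Microglia and macrophage markers in mouse at 72 h rose (15 of 18 rose, 15 rose adjusted within the list, adjusted p = 2.65e-19, adjusted p = 0.00243 with an estimated correlation), with Tyrobp (2.71 ± 0.21) and Ctss (1.76 ± 0.13). Complement genes rose (5 of 10 rose, 5 rose adjusted within the list, adjusted p = 8.36e-07, adjusted p = 0.0224 with an estimated correlation), with C1qc (2.61 ± 0.18) and C1qb (2.48 ± 0.14). Reactive astrocyte markers rose (14 of 16 rose, 14 rose and 1 fell adjusted within the list, adjusted p = 2.07e-15, adjusted p = 0.00554 with an estimated correlation), with Serpina3n (3.69 ± 0.25) and Nes (2.16 ± 0.17). Fibroblast and matrix genes rose (14 of 20 rose and 1 fell, 14 rose and 1 fell adjusted within the list, adjusted p = 8.10e-09, adjusted p = 0.00831 with an estimated correlation), with the collagen gene Col3a1 (3.19 ± 0.40) and Bgn (1.99 ± 0.19). Endothelial and pericyte markers rose (10 of 18 rose, 10 rose adjusted within the list, adjusted p = 1.42e-06, adjusted p = 0.00554 with an estimated correlation), with Vwf (2.02 ± 0.31). Cell cycle genes rose (15 of 22 rose, 17 rose and 1 fell adjusted within the list, adjusted p = 4.08e-09, adjusted p = 0.00639 with an estimated correlation), with the nucleotide reductase gene Rrm2 (2.39 ± 0.39). Antigen presentation genes rose (7 of 13 rose, 7 rose adjusted within the list, adjusted p = 3.83e-05, adjusted p = 0.0212 with an estimated correlation), with B2m (2.21 ± 0.25). Interferon response genes rose (6 of 10 rose, 6 rose adjusted within the list, adjusted p = 9.29e-06, adjusted p = 0.0464 with an estimated correlation), with Gbp2 (3.26 ± 0.35). Oxidative stress genes rose (6 of 19 rose, 8 rose adjusted within the list, adjusted p = 0.00191, adjusted p = 0.0239 with an estimated correlation), with Hmox1 (2.81 ± 0.21).

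Neuronal and synaptic genes were lower as a list in mouse at 72 h (5 of 25 fell, 5 fell adjusted within the list, adjusted p = 0.032, adjusted p = 0.397 with an estimated correlation). The list had adjusted p = 0.0695 without injury 3, 0.91 without sham 1c and 0.0602 after quantile normalization. The glutamate receptor subunit gene Gria2 (-0.82 ± 0.18, adjusted p = 0.00332) was among them. With the preset correlation only, adhesion and protease genes were higher (9 of 14 rose, 9 rose adjusted within the list, adjusted p = 2.85e-05, adjusted p = 0.0965 with an estimated correlation). Oligodendrocyte markers were higher too (7 of 10 rose, 7 rose adjusted within the list, adjusted p = 0.000141, adjusted p = 0.0965 with an estimated correlation), with Mag (1.10 ± 0.21). The cytokine list was higher (6 of 15 rose and 1 fell, 7 rose and 2 fell adjusted within the list, adjusted p = 0.00263, adjusted p = 0.191 with an estimated correlation), with Ccl12 (3.72 ± 0.47).

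**Figure D3:**
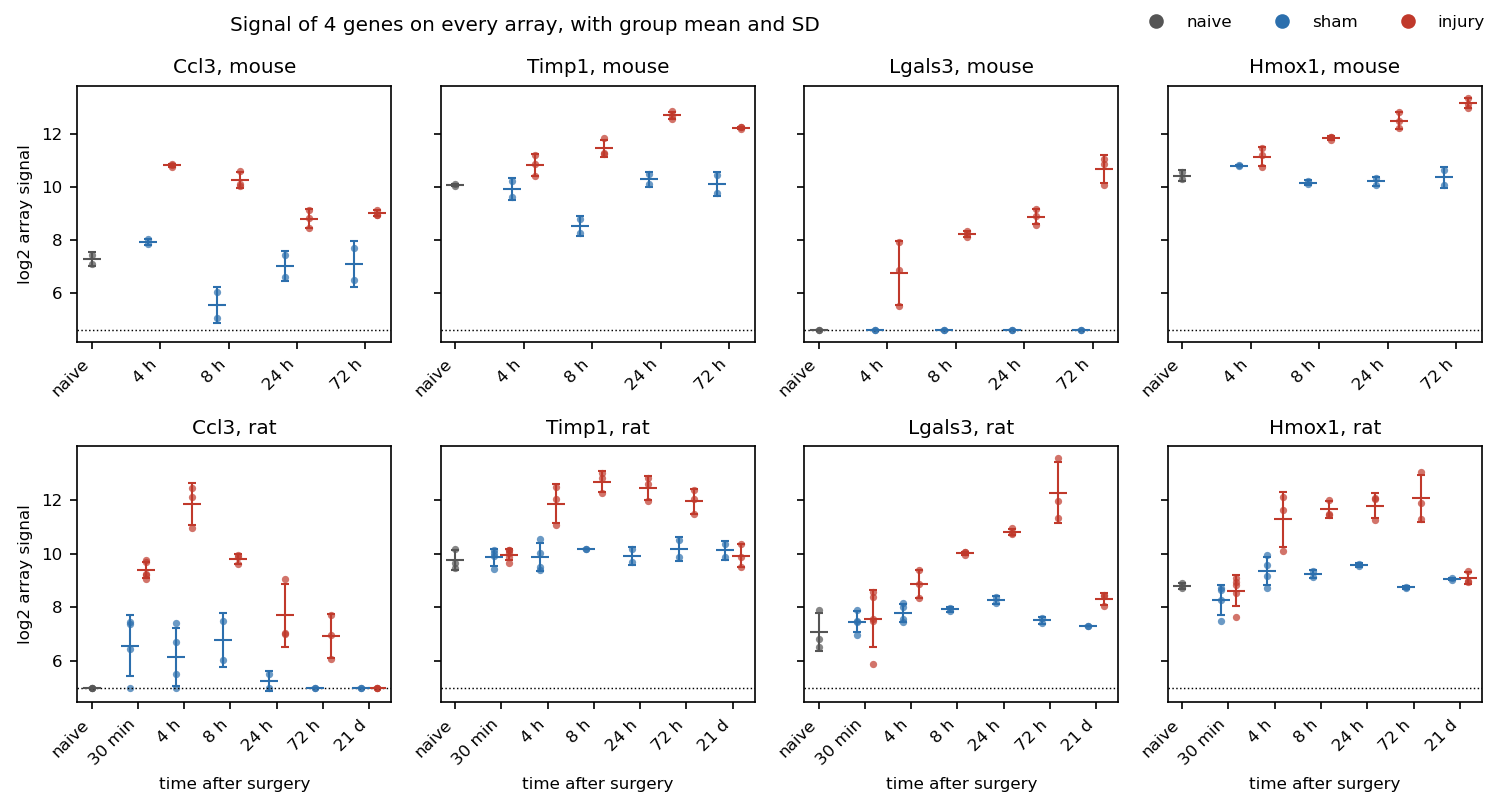
Log2 signal per array of Ccl3, Timp1, Lgals3 and Hmox1 by time in naive, sham and injury samples, mouse above and rat below, with group mean and standard deviation. The dotted line is the floor, at which the mouse sham arrays lie for Lgals3.

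The injury effect at 72 h minus that at 4 h tested which mouse changes grew or shrank, and 332 genes were called (229 higher at 72 h, 103 lower). Effects were larger at 72 h for Klk6 (at least 6.24 ± 0.62, adjusted p = 4.77e-06), Arg1 (5.02 ± 0.88, adjusted p = 0.00193), Lyz2 (4.71 ± 0.46, adjusted p = 4.20e-06) and the integrin gene Itgam (4.61 ± 0.82, adjusted p = 0.00227). The chemokine gene Cxcl2 (-3.81 ± 0.80, adjusted p = 0.00744) had a smaller effect at 72 h, with adjusted p = 0.0704 with averaged sham arrays. Il1b did too (-2.85 ± 0.73, adjusted p = 0.0252), with adjusted p = 0.0759 without injury 4 h 1, 0.122 without sham 4 h 1b, 0.0567 without injury 4 h 3 and 0.127 with averaged sham arrays. The count was 772 without sham 72 h replicate 1c, 176 without sham 4 h replicate 1c, 207 without sham 72 h replicate 1d and 207 without sham 4 h replicate 1b. With the sham arrays averaged it was 80.

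Effects on microglia and macrophage markers were larger at 72 h (13 of 18 larger, 14 larger and 1 smaller adjusted within the list, adjusted p = 2.76e-16, adjusted p = 0.00246 with an estimated correlation). Those on cell cycle genes were larger (9 of 22 larger, 13 larger adjusted within the list, adjusted p = 3.04e-09, adjusted p = 0.00385 with an estimated correlation). So were those on reactive astrocyte markers (7 of 16 larger, 9 larger adjusted within the list, adjusted p = 1.32e-09, adjusted p = 0.00895 with an estimated correlation). Fibroblast and matrix genes had larger effects (11 of 20 larger and 1 smaller, 13 larger and 1 smaller adjusted within the list, adjusted p = 9.67e-09, adjusted p = 0.00481 with an estimated correlation). Complement genes had larger effects (3 of 10 larger, 4 larger adjusted within the list, adjusted p = 3.72e-07, adjusted p = 0.00895 with an estimated correlation), as did endothelial markers (2 of 18 larger, 8 larger adjusted within the list, adjusted p = 4.83e-06, adjusted p = 0.00357 with an estimated correlation). Oxidative stress genes had larger effects (4 of 19 larger, 7 larger adjusted within the list, adjusted p = 0.000907, adjusted p = 0.00895 with an estimated correlation), as did antigen presentation genes (4 of 13 larger, 7 larger adjusted within the list, adjusted p = 0.000274, adjusted p = 0.0165 with an estimated correlation). Red blood cell markers had smaller effects (2 of 4 smaller, 2 smaller adjusted within the list, adjusted p = 0.0038, adjusted p = 0.0214 with an estimated correlation). With the preset correlation only, oligodendrocyte (1 of 10 larger, 6 larger adjusted within the list, adjusted p = 0.00181, adjusted p = 0.148 with an estimated correlation) and interferon genes (2 of 10 larger, 4 larger adjusted within the list, adjusted p = 0.00107, adjusted p = 0.102 with an estimated correlation) had larger and immediate early genes (3 of 24 smaller, 4 smaller adjusted within the list, adjusted p = 0.0139, adjusted p = 0.428 with an estimated correlation) smaller effects.

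Sham against naive in mouse asked what surgery without injury did, and 7 genes were called. Higher in sham were Lbp (1.72 ± 0.27, adjusted p = 0.0254), Ptov1 (0.98 ± 0.17, adjusted p = 0.0254), Slc2a1 (0.96 ± 0.16, adjusted p = 0.0254) and the matrix gene Dcn (0.85 ± 0.16, adjusted p = 0.0494). Lower were Ywhaz (-1.37 ± 0.25, adjusted p = 0.0393), the creatine kinase gene Ckb (-1.16 ± 0.22, adjusted p = 0.0494) and the enkephalin precursor gene Penk (-0.71 ± 0.14, adjusted p = 0.0494). None of the 7 calls was kept with every array left out in turn. The count was 0 without sham 4 h replicate 1b or sham 8 h replicate 1b, 1 without naive replicate 2, and 11 without naive replicate 1. It was 19 without sham 24 h replicate 1c, 3 without sham 24 h replicate 1d and 2 without sham 72 h replicate 1d. Quantile normalization gave 4 rises and 0 falls where the deposited scale gave 4 and 3. The mean of a gene's probe sets gave 2 genes, and no filter or averaged sham arrays gave 0. Neuronal genes were lower as a list (0 of 25 called, 1 fell adjusted within the list, adjusted p = 0.0451, adjusted p = 0.434 with an estimated correlation). The call had adjusted p from 0.0539 to 0.724 without sham 24 h 1c, without naive 1, without sham 4 h 1c, without sham 72 h 1d, without sham 8 h 1b and after quantile normalization.

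At 30 min in rat, the chemokine gene Ccl3 was the single call: 2.83 ± 0.49, adjusted p = 0.0094, with a signal of 673 in injury and 94.8 in sham (5 and 4 samples). It had adjusted p = 0.194 without sham 3, 0.402 with only the compared groups, 0.074 with the replicate block and 0.114 without the 4 arrays. Its change without the 4 was 2.22 ± 0.45, and no gene was called there. At raw p below 0.05, 132 genes passed with all arrays and 108 without the 4 (limma). Cytokines and chemokines were higher as a list (1 of 14 rose, 1 rose adjusted within the list, adjusted p = 2.83e-05, adjusted p = 0.104 with an estimated correlation). Immediate early genes were higher (0 of 23 called, 0 adjusted within the list, adjusted p = 0.00156, adjusted p = 0.135 with an estimated correlation). It had adjusted p = 0.0556 without injury 4, 0.0654 without sham 3 and 0.0647 without the 4 arrays. The gene count was 2 without injury replicate 4 or sham replicate 2, 0 without sham replicate 3, and 3 against all uninjured arrays.

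At 4 h in rat, genes of chemokines, the cytokine Il1b and the heat shock protein Hspa1a rose. Ccl3 (5.69 ± 0.56, adjusted p = 5.96e-08) and the inducible heat shock gene Hspa1a (3.87 ± 0.67, adjusted p = 0.00152) rose most, with the chemokines Cxcl2 (3.82 ± 0.71, adjusted p = 0.00234) and Ccl4 (3.46 ± 0.65, adjusted p = 0.00234). The inflammatory cytokine Il1b (2.78 ± 0.45, adjusted p = 0.000547) and the protease inhibitor gene Timp1 (1.98 ± 0.32, adjusted p = 0.000547) rose too. Each kept its call without any 1 array and without the 4 arrays, where Ccl3 had 6.59 ± 0.53, adjusted p = 1.59e-09, Hspa1a 4.20 ± 0.78, adjusted p = 0.00302 and Ccl4 4.54 ± 0.69, adjusted p = 0.000347. There Il1b had 3.44 ± 0.38, adjusted p = 9.31e-07, Timp1 2.08 ± 0.35, adjusted p = 0.00108 and Cxcl2 adjusted p = 0.000119. The hemoglobin genes Hbb (2.36 ± 0.45, adjusted p = 0.00253) and Hbb-b1 (1.93 ± 0.37, adjusted p = 0.00248) were called with all arrays, and without the 4 had adjusted p = 0.126 and 0.0934. Among falls, the dopamine receptor gene Drd2 (-2.66 ± 0.59, adjusted p = 0.0131) was called and had -2.84 ± 0.63, adjusted p = 0.0181 without the 4 arrays. Drd2 had adjusted p = 0.0567 without injury 1 and 0.0853 without injury 2. Ccl3 had adjusted p = 0.058 with the letter block. Cxcl2, Hspa1a, Il1b, Ccl4 and Drd2 had adjusted p = 0.730 with the letter block and 0.354 to 0.356 with only the compared groups. Timp1 had 0.134 and 0.401 in these fits. Drd2 also had 0.222 against all uninjured arrays and 0.0955 with the antisense covariate.

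The rat 4 h count was 204 genes (120 rose, 84 fell), and 44 without the 4 arrays (37 rose, 7 fell), of which 29 were shared in direction. Sham replicates 3 and 4 at this time are among the 4 arrays. The count was 36, 19 and 80 without injury replicates 1, 2 and 3. It was 1076, 1133, 39 and 35 without sham replicates 1 to 4. Only the compared groups gave 1, the title letter as a block 0, no filter 99, all uninjured arrays 48 and the antisense covariate 28. All 3 injury arrays at 4 h carry the letter b and all 4 sham arrays a. Only injury 21 d has both, with b in replicate 1, so the block difference rested on that array. The median change of all genes was −0.12 on the deposited scale and 0.01 after quantile normalization.

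Cytokines and chemokines in rat at 4 h were higher (7 of 14 rose, 8 rose adjusted within the list, adjusted p = 1.83e-06, adjusted p = 0.0718 with an estimated correlation). Immediate early genes were higher (5 of 23 rose, 6 rose adjusted within the list, adjusted p = 0.000802, adjusted p = 0.122 with an estimated correlation). Red blood cell markers rose (3 of 4 rose, 3 rose adjusted within the list, adjusted p = 0.00127, adjusted p = 0.0173 with an estimated correlation). Without the 4 arrays these lists were called with both correlations: adjusted p = 0.00064, 0.0469 and 0.0263 with an estimated correlation. Heat shock genes were higher (1 of 14 rose, 6 rose adjusted within the list, adjusted p = 0.00588, adjusted p = 0.306 with an estimated correlation). This list had adjusted p = 0.0519 without injury 2. Control probe sets for antisense actin and GAPDH averaged 7.25 in injury 4 h, 9.06 in sham 4 h and 6.79 in naive rats.

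Further rat lists at 4 h were called with all arrays but not without the 4. Endothelial and pericyte markers were lower (1 of 13 fell, 4 fell adjusted within the list, adjusted p = 0.0341, adjusted p = 0.303 with an estimated correlation). The same list had adjusted p = 0.0753 without sham 4, 0.323 without the 4 arrays and 0.0504 with the antisense covariate. Fibroblast and matrix genes were lower (2 of 15 fell, 1 rose and 4 fell adjusted within the list, adjusted p = 0.0429, adjusted p = 0.465 with an estimated correlation). This call had adjusted p from 0.0504 to 0.34 without injury 1 or 3, sham 2 or 4 or the 4 arrays. The same held with no filter and with the antisense covariate. Neuronal genes were higher (0 of 29 called, 0 adjusted within the list, adjusted p = 0.0441, adjusted p = 0.465 with an estimated correlation). The group had adjusted p from 0.106 to 0.888 without injury 3, without sham 4, without sham 3, after quantile normalization, without the 4 arrays and with the antisense covariate. Without the 4 arrays the list pointed lower (adjusted p = 0.888). Hypoxia and glycolysis genes were higher (1 of 18 rose, 2 rose adjusted within the list, adjusted p = 0.0142, adjusted p = 0.133 with an estimated correlation). That list had adjusted p = 0.0626 without sham 3, 0.208 after quantile normalization and 0.396 without the 4 arrays. Cholesterol synthesis genes were higher (1 of 13 rose, 8 rose and 2 fell adjusted within the list, adjusted p = 0.0226, adjusted p = 0.22 with an estimated correlation). The list had adjusted p = 0.102 without the 4 arrays.

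At 8 h in rat, 29 genes were called (25 rose, 4 fell), and 73 without the 4 arrays (59 rose, 14 fell, all 29 shared). Antisense control probe sets averaged 9.18 in injury and 7.40 in sham at this time. Osteopontin, Spp1 (4.67 ± 0.66, adjusted p = 0.000101), the iron-binding gene Lcn2 (4.12 ± 0.54, adjusted p = 4.68e-05) and Timp1 (2.53 ± 0.38, adjusted p = 0.000185) kept their calls with every array left out. The myeloid genes S100a8 (4.83 ± 0.87, adjusted p = 0.00192) and S100a9 (4.29 ± 0.76, adjusted p = 0.00151) and the chemokine gene Ccl2 (4.62 ± 0.76, adjusted p = 0.000576) rose. S100a8 had adjusted p = 0.0527 without sham 2, S100a9 adjusted p = 0.0983 without sham 2 and Ccl2 adjusted p = 0.0567 without sham 2. The glutamate receptor gene Grm3 (-1.47 ± 0.33, adjusted p = 0.0264) fell, but lost its call without any 1 of the 5 arrays (adjusted p from 0.0597 to 0.223). The count was 10 without sham replicate 2, 11 without injury replicate 3, 13 without injury replicate 2 and 14 without injury replicate 1. It was 48 with only the compared groups, 79 against all uninjured arrays, 19 with the title letter as a block and 12 with the antisense covariate.

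Reactive astrocyte markers in rat at 8 h rose (3 of 12 rose, 6 rose adjusted within the list, adjusted p = 8.16e-12, adjusted p = 0.0050 with an estimated correlation). Red blood cell markers rose (1 of 4 rose, 3 rose adjusted within the list, adjusted p = 0.000465, adjusted p = 0.0143 with an estimated correlation). With the preset correlation only, cytokines and chemokines were higher (2 of 14 rose, 3 rose adjusted within the list, adjusted p = 0.000136, adjusted p = 0.133 with an estimated correlation). Adhesion and protease genes were higher (2 of 18 rose, 4 rose adjusted within the list, adjusted p = 1.49e-06, adjusted p = 0.0597 with an estimated correlation), and without the 4 arrays had adjusted p = 0.0469 with an estimated correlation. Microglia and macrophage markers were higher (2 of 13 rose and 1 fell, 5 rose and 1 fell adjusted within the list, adjusted p = 0.00244, adjusted p = 0.099 with an estimated correlation). Cell death and p53 genes were higher (1 of 12 rose, 2 rose adjusted within the list, adjusted p = 0.00635, adjusted p = 0.181 with an estimated correlation), as were antigen presentation genes (0 of 12 called, 2 rose adjusted within the list, adjusted p = 0.000465, adjusted p = 0.0663 with an estimated correlation). Interferon response genes were higher (1 of 9 rose, 3 rose adjusted within the list, adjusted p = 0.00016, adjusted p = 0.0846 with an estimated correlation). Inhibitory neuron genes were lower (0 of 19 called, 3 fell adjusted within the list, adjusted p = 0.0142, adjusted p = 0.172 with an estimated correlation). The call had adjusted p = 0.10 without sham 1 and 0.206 with the antisense covariate. Heat shock genes were higher (0 of 14 called, 2 rose adjusted within the list, adjusted p = 0.0424, adjusted p = 0.467 with an estimated correlation). It had adjusted p = 0.198 without sham 1, 0.307 without injury 1 and 0.0704 without the 4 arrays.

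At 24 h in rat, 11 genes rose and 0 fell, and 34 were called without the 4 arrays (30 rose, 4 fell). Osteopontin, Spp1 (4.92 ± 0.66, adjusted p = 3.46e-05), Lcn2 (4.21 ± 0.54, adjusted p = 2.98e-05), Timp1 (2.53 ± 0.38, adjusted p = 0.000136) and the interferon-inducible gene Ifitm3 (1.88 ± 0.28, adjusted p = 0.000136) kept their calls with every array left out. The cell surface gene Cd44 (3.79 ± 0.66, adjusted p = 0.00166) rose, with adjusted p = 0.0816 without sham 2 and 0.476 with the mean of probe sets. The reactive astrocyte list rose (2 of 12 rose, 6 rose adjusted within the list, adjusted p = 4.08e-18, adjusted p = 0.000345 with an estimated correlation). The microglia and macrophage list rose (3 of 13 rose, 4 rose adjusted within the list, adjusted p = 3.39e-06, adjusted p = 0.0173 with an estimated correlation). Heat shock genes rose (1 of 14 rose, 6 rose adjusted within the list, adjusted p = 6.75e-11, adjusted p = 0.0173 with an estimated correlation), but without the 4 arrays had adjusted p = 0.0686 with an estimated correlation. Antisense control probe sets averaged 9.51 in injury and 9.11 in sham at this time. The gene count was 7 without injury replicate 3, 5 without sham replicate 1 or sham replicate 2, 20 without injury replicate 2, 24 after quantile normalization and 462 against all uninjured arrays.

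Other rat lists at 24 h passed with the preset correlation only. Oxidative stress genes were higher (1 of 17 rose, 1 rose adjusted within the list, adjusted p = 0.00459, adjusted p = 0.0628 with an estimated correlation), as were antigen presentation genes (0 of 12 called, 1 rose adjusted within the list, adjusted p = 0.00258, adjusted p = 0.104 with an estimated correlation). Interferon genes were higher (1 of 9 rose, 1 rose adjusted within the list, adjusted p = 0.00631, adjusted p = 0.22 with an estimated correlation). Neuronal genes were lower (0 of 29 called, 0 adjusted within the list, adjusted p = 0.00016, adjusted p = 0.133 with an estimated correlation), as were inhibitory neuron genes (0 of 19 called, 1 fell adjusted within the list, adjusted p = 0.00127, adjusted p = 0.0776 with an estimated correlation). Immediate early genes were higher (0 of 23 called, 0 adjusted within the list, adjusted p = 0.017, adjusted p = 0.291 with an estimated correlation). This list had adjusted p = 0.321 without injury 3 and 0.0878 without sham 1. Adhesion genes were higher (1 of 18 rose, 1 rose adjusted within the list, adjusted p = 0.00497, adjusted p = 0.245 with an estimated correlation). The same list had adjusted p = 0.0744 without sham 1. Cell cycle genes were higher (0 of 13 called, 3 rose adjusted within the list, adjusted p = 0.0212, adjusted p = 0.303 with an estimated correlation). This call had adjusted p = 0.113 without injury 2. Astrocyte markers at rest were lower (0 of 13 called, 0 adjusted within the list, adjusted p = 0.0429, adjusted p = 0.226 with an estimated correlation). The group had adjusted p = 0.173 without injury 3, 0.0843 without injury 2, 0.18 without sham 2, 0.0997 after quantile normalization and 0.102 with the replicate block. The oligodendrocyte list was lower (0 of 11 called, 0 adjusted within the list, adjusted p = 0.0417, adjusted p = 0.499 with an estimated correlation). That list had adjusted p = 0.0618 without injury 1, 0.216 without injury 3, 0.116 without sham 1, 0.122 with the replicate block and 0.0658 with the antisense covariate. Ion channel genes were lower (0 of 25 called, 0 adjusted within the list, adjusted p = 0.0441, adjusted p = 0.306 with an estimated correlation). The list had adjusted p from 0.0525 to 0.327 without injury 1, without injury 3, without sham 1, with no filter, with the replicate block, without the 4 arrays and with the antisense covariate.

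At 72 h in rat, macrophage and cell cycle genes rose, while antisense control probe sets averaged 8.48 in injury and 5.36 in sham (3 and 2 arrays). Osteopontin, Spp1 (6.94 ± 0.66, adjusted p = 2.40e-08), Lgals3 (4.76 ± 0.54, adjusted p = 9.87e-07), Apobec1 (at least 4.46 ± 0.53, adjusted p = 1.26e-06) and the lipid droplet gene Plin2 (4.30 ± 0.64, adjusted p = 7.65e-05) rose most and kept their calls with every array left out. The lysozyme gene Lyz2 (2.92 ± 0.36, adjusted p = 2.50e-06) and the intermediate filament gene Vim (2.83 ± 0.45, adjusted p = 0.000192) did so too. The same held for Hmox1 (3.34 ± 0.47, adjusted p = 4.32e-05) and the topoisomerase gene Top2a (2.98 ± 0.47, adjusted p = 0.00017), though Hmox1 had adjusted p = 0.0535 with the antisense covariate, and Top2a had adjusted p = 0.0594 with the mean of probe sets and 0.0622 with the antisense covariate. Called were 113 genes (86 rose, 27 fell), and 376 without the 4 arrays (217 rose, 159 fell, all 113 shared). The count was 19 without sham replicate 1, 22 without sham replicate 2, 326 without injury replicate 1, 41 without injury replicate 2 and 18 without injury replicate 3. It was 62 after quantile normalization (52 rose, 10 fell, 58 shared), 19 with only the compared groups, 239 against all uninjured arrays and 11 with the antisense covariate. The median change of all genes was 0.07 on the deposited scale and −0.07 after quantile normalization.

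Named falls in rat at 72 h rested on few arrays. The apolipoprotein gene Apoe (-3.33 ± 0.93, adjusted p = 0.0446) had adjusted p = 0.382 without sham 1, 0.0534 without injury 2, 0.194 without sham 2 and 0.394 without injury 3, and its change was 0.13 after quantile normalization. The neurofilament gene Nefm (-1.96 ± 0.43, adjusted p = 0.00956) had adjusted p = 0.125 without sham 1, 0.0518 without injury 2, 0.125 without sham 2 and 0.0954 without injury 3.

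Markers of microglia and macrophages in rat at 72 h rose (7 of 13 rose, 9 rose adjusted within the list, adjusted p = 2.57e-14, adjusted p = 0.000345 with an estimated correlation). Antigen presentation genes rose (5 of 12 rose, 9 rose adjusted within the list, adjusted p = 2.28e-07, adjusted p = 0.012 with an estimated correlation). Reactive astrocyte markers rose (5 of 12 rose, 8 rose adjusted within the list, adjusted p = 1.33e-08, adjusted p = 0.0164 with an estimated correlation). Cell cycle genes rose (4 of 13 rose, 5 rose adjusted within the list, adjusted p = 8.57e-07, adjusted p = 0.0318 with an estimated correlation). Neuronal and synaptic genes were lower (2 of 29 fell, 8 fell adjusted within the list, adjusted p = 1.18e-06, adjusted p = 0.0628 with an estimated correlation), and without the 4 arrays had adjusted p = 0.0469 with an estimated correlation. With the preset correlation only, ion channel genes were lower (1 of 25 fell, 3 fell adjusted within the list, adjusted p = 0.00016, adjusted p = 0.0628 with an estimated correlation). Inhibitory neuron genes were lower (0 of 19 called, 1 fell adjusted within the list, adjusted p = 0.000543, adjusted p = 0.0628 with an estimated correlation). The call had adjusted p = 0.206 with the antisense covariate. Complement genes were higher (1 of 9 rose, 2 rose adjusted within the list, adjusted p = 0.00988, adjusted p = 0.0573 with an estimated correlation), but without the 4 arrays had adjusted p = 0.0469 with an estimated correlation. It had adjusted p = 0.0583 without injury 1.

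The remaining lists called in rat at 72 h also held with the preset correlation only. Adhesion and protease genes were higher (4 of 18 rose, 5 rose adjusted within the list, adjusted p = 0.00984, adjusted p = 0.291 with an estimated correlation). This list had adjusted p = 0.18 with the antisense covariate. The fibroblast list was higher (2 of 15 rose, 3 rose and 1 fell adjusted within the list, adjusted p = 0.0462, adjusted p = 0.465 with an estimated correlation). The same list had adjusted p from 0.0542 to 0.142 without sham 1, without injury 1, without injury 3, with no filter, with the replicate block, without the 4 arrays and with the antisense covariate. Oxidative stress genes were higher (1 of 17 rose, 3 rose adjusted within the list, adjusted p = 0.0355, adjusted p = 0.135 with an estimated correlation). This call had adjusted p = 0.0588 without sham 2, 0.0643 without injury 1, 0.143 without injury 3 and 0.0631 with the antisense covariate. Oxidative phosphorylation genes were lower (0 of 22 called, 0 adjusted within the list, adjusted p = 0.0142, adjusted p = 0.352 with an estimated correlation). The group had adjusted p = 0.0912 without sham 1, 0.151 without injury 2, 0.288 after quantile normalization and 0.441 with the antisense covariate. The cholesterol list was lower (2 of 13 fell, 2 fell adjusted within the list, adjusted p = 0.0134, adjusted p = 0.172 with an estimated correlation). That list had adjusted p = 0.0643 without injury 1 and 0.0577 with the antisense covariate.

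At 21 d in rat, no gene was called by limma, with 50 genes at raw p below 0.05 (49 after quantile normalization, 127 without the 4 arrays). Immediate early genes were lower as a list (0 of 23 called, 0 adjusted within the list, adjusted p = 5.34e-05, adjusted p = 0.0671 with an estimated correlation). The antigen presentation list was higher (0 of 12 called, 0 adjusted within the list, adjusted p = 0.00432, adjusted p = 0.122 with an estimated correlation). The list had adjusted p = 0.0901 without sham 1. The microglia and macrophage list was higher (0 of 13 called, 0 adjusted within the list, adjusted p = 0.0441, adjusted p = 0.291 with an estimated correlation). The call had adjusted p from 0.0525 to 0.34 without injury 3, without injury 2, without injury 1, without sham 1, with no filter, with the replicate block, without the 4 arrays and with the antisense covariate.

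The rat injury effect at 72 h minus that at 4 h gave 193 called genes (115 larger at 72 h, 78 smaller), and 89 without the 4 arrays (59 and 30, 65 shared). The editing enzyme gene Apobec1 (at least 5.76 ± 0.68, adjusted p = 4.64e-06) was larger at 72 h, with adjusted p = 0.189 with the letter block. Rasl11b (-4.72 ± 0.91, adjusted p = 0.00533) was smaller, with adjusted p = 0.351 with the letter block and 0.804 with the antisense covariate. Effects on microglia and macrophage markers were larger at 72 h (6 of 13 larger, 9 larger adjusted within the list, adjusted p = 3.00e-06, adjusted p = 0.0146 with an estimated correlation). Of the lists called with the preset correlation only, cell cycle genes were larger (4 of 13 larger, 6 larger adjusted within the list, adjusted p = 9.17e-06, adjusted p = 0.0607 with an estimated correlation). Neuronal genes had smaller effects (5 of 29 smaller, 9 smaller adjusted within the list, adjusted p = 4.41e-06, adjusted p = 0.0749 with an estimated correlation), as did cytokines (5 of 14 smaller, 6 smaller adjusted within the list, adjusted p = 0.0122, adjusted p = 0.239 with an estimated correlation). Cholesterol synthesis genes had smaller effects (4 of 13 smaller, 1 larger and 8 smaller adjusted within the list, adjusted p = 0.00178, adjusted p = 0.0791 with an estimated correlation). The median difference over all genes was 0.23 on the deposited scale and −0.08 after quantile normalization.

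That rat difference changed with single arrays and settings. The count was 101, 89 and 63 without injury 4 h replicates 1, 2 and 3, and 672, 581, 96 and 108 without sham 4 h replicates 1 to 4. It was 567, 42 and 33 without injury 72 h replicates 1, 2 and 3, and 13 and 26 without sham 72 h replicates 1 and 2. Quantile normalization gave 117 genes, the antisense covariate 3 and the title letter block, which parts injury from sham at 4 h, 0.

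Sham against naive in rat gave 1 called gene, the NF-kappa-B inhibitor gene Nfkbia (1.21 ± 0.22, adjusted p = 0.0144), with 218 genes at raw p below 0.05. Nfkbia had adjusted p = 0.0885 without naive 3, 0.203 without naive 2 and 0.603 without naive 1. The count was 2 without sham 4 h replicate 4, 2 without the 4 arrays, and 0 after quantile normalization, with the title letter block or with the antisense covariate. With the mean of probe sets the 1 call was a fall of another gene, and Nfkbia had adjusted p = 0.791. Neuronal genes were lower in sham (0 of 29 called, 1 fell adjusted within the list, adjusted p = 7.10e-07, adjusted p = 0.0628 with an estimated correlation), and without the 4 arrays had adjusted p = 0.0469 with an estimated correlation. Astrocyte markers at rest were lower (0 of 13 called, 0 adjusted within the list, adjusted p = 0.00631, adjusted p = 0.099 with an estimated correlation), as were ion channels (0 of 25 called, 0 adjusted within the list, adjusted p = 0.00127, adjusted p = 0.099 with an estimated correlation). Complement genes were higher (0 of 9 called, 0 adjusted within the list, adjusted p = 0.0333, adjusted p = 0.0846 with an estimated correlation), but without the 4 arrays had adjusted p = 0.0469 with an estimated correlation. It had adjusted p = 0.0597 without sham 21 d 2 and 0.0906 without naive 1. Antigen presentation was higher (0 of 12 called, 0 adjusted within the list, adjusted p = 0.0443, adjusted p = 0.302 with an estimated correlation). This list had adjusted p from 0.0503 to 0.183 without sham 8 h 2, without sham 72 h 2, without sham 4 h 2, without sham 30 min 2, without sham 30 min 1, without sham 21 d 2, without naive 2, without sham 24 h 2, without sham 30 min 3, without sham 4 h 1, after quantile normalization, with no filter, without the 4 arrays and with the antisense covariate. Inhibitory neuron genes were lower (0 of 19 called, 0 adjusted within the list, adjusted p = 0.0443, adjusted p = 0.291 with an estimated correlation). The same list had adjusted p from 0.0516 to 0.451 without sham 8 h 2, without naive 3, without sham 72 h 1, without sham 30 min 2, without sham 21 d 2, without sham 24 h 2, without sham 30 min 3, without sham 4 h 4, without sham 4 h 3, after quantile normalization, with the replicate block, without the 4 arrays and with the antisense covariate.

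**Figure D4:**
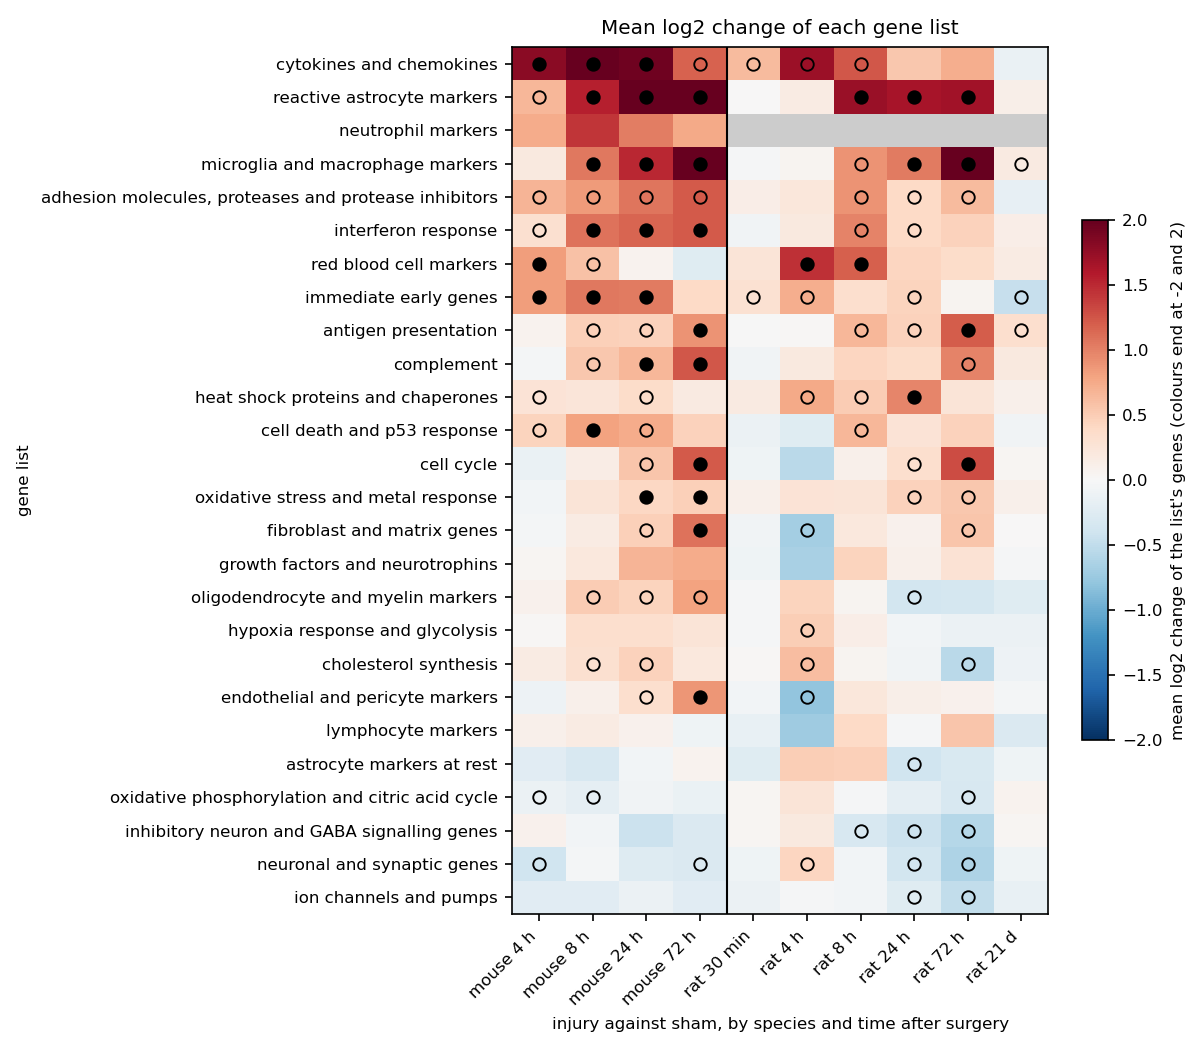
Mean log2 change of each gene list (vertical) in each contrast (horizontal) for mouse and rat. Open circles mark lists called by camera with the preset correlation, filled circles lists called also with an estimated correlation, and grey fields lists not tested.

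Some lists were called in no injury contrast, and their smallest camera adjusted p follows. Lymphocyte markers had 0.383 in mouse (1 of 6 rose at 8 h) and 0.308 in rat. Growth factor genes had 0.0634 in mouse (5 of 15 rose at 24 h) and 0.0746 in rat. In mouse, neutrophil markers had 0.0763 (2 of 5 rose at 8 h) and hypoxia and glycolysis genes 0.0505 (3 of 20 rose at 24 h). Mouse inhibitory neuron genes had 0.073 (4 of 16 fell at 72 h), ion channels 0.073 (3 of 18 fell at 72 h) and astrocyte markers at rest 0.0918. The neutrophil list was not tested in rat, where fewer than 4 of its genes were measured.

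The species were compared to see which injury changes both showed, over 2191 genes tested in both. At 4 h, 14 genes rose in both (1.04 by chance, Fisher's exact p = 4.35e-14), among them the chemokine Ccl3 (2.88 in mouse, 5.69 in rat). At 8 h, 14 rose in both (1.36 by chance, Fisher's exact p = 6.81e-13), among them Timp1 (2.92 and 2.53). At 24 h, 7 rose in both (0.895 by chance, Fisher's exact p = 3.94e-06), among them Timp1 (2.42 and 2.53) and Ifitm3 (2.18 and 1.88). At 72 h, 41 rose in both (7.26 by chance, Fisher's exact p = 1.23e-25), among them Lgals3 (at least 6.08 and 4.76), Lyz2 (5.37 and 2.92) and Hmox1 (2.81 and 3.34). Genes that fell in both were 0 at 4 h (0.11 by chance) and 4 at 72 h (1.25 by chance, Fisher's exact p = 0.0320). At 8 and 24 h no rat fall was among these genes, so none could be shared. No gene was called in opposite directions.

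Across all 2191 genes the changes in mouse and rat had Pearson r of 0.178, 0.363, 0.355 and 0.426 and Spearman rho of 0.109, 0.207, 0.265 and 0.355 at 4, 8, 24 and 72 h. Mouse 4 h had a rho of 0.225 with rat 24 h, and mouse 24 h 0.273 with rat 8 h, both above their time-matched values. Of the mouse calls measured in rat, 22 of 30, 167 of 227, 239 of 316 and 330 of 423 had the same sign there. Genes that rose in mouse at 24 h and at 72 h numbered 265 in common (38.8 by chance), and those that fell 112 (16.2 by chance). In rat, 11 genes rose at both 8 h and 72 h (0.526 by chance), while changes at 4 h had a rho of −0.184 with those at 8 h and −0.246 with those at 72 h (1 and 2 genes called in opposite directions). No test was made of these time overlaps.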

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

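The split counts, the species sharing of rat 4 h genes, the sham pool test and the comparison with the 24 h sham arrays were set before the result they test was seen. The tests against 2 rat sham arrays, of other pituitary genes and of rat 72 h sharing with mouse were chosen only after it was seen.

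Rat 4 h calls may reflect the pair of sham arrays that stood apart, an injury response, or both. Of 35 splits of the 7 arrays, 6 called at least the real 204 genes, so chance cannot be excluded for this count, which tests no single gene; the highest other split called 1451 genes, for injury replicate 1 with sham replicates 3 and 4, which points to a structure of the samples. Against sham replicates 1 and 2 alone, the 120 rises had a median of 0.70 and the 84 falls −0.78 (quartiles −1.19 to −0.61). The full fit gave 1.71 and −1.50, and replicates 3 and 4 alone 2.37 and −2.31. The rises met the written bound and the falls sat near it. The calls used replicates 3 and 4, so some shrinkage was built in and neither median can tell. Of the rises tested in mouse, 72.6% (69 of 95) had the same sign there, and of the falls 60% (24 of 40), against 53.4% of all genes, and neither tells the explanations apart. The bound for ruling an explanation out was made stricter after these values were seen, which moved both results on falls to undecided.

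Pituitary genes in the mouse sham 4 h arrays could come from pituitary tissue in that sample. A shared RNA pool would explain only why both arrays agree. Of 9 other pituitary genes, 3 (Tshb, Fshb and Ghrhr) were above every other mouse array in both, but growth hormone was not, so the test was undecided. In both, 5 probe sets (of Prl, Pomc, Cga and Tshb) were at least 2-fold above every other array, and 0 in each other sham pair. Sham pairs differed 1.20 times as much as injury pairs over the 50 genes that varied most between uninjured rat arrays, and 0.993 times over all genes. That variance includes array noise, which 2 arrays of 1 pool would also show, so this comparison cannot tell. The gene Ttr alone, noticed before that test, pointed to a shared pool (median difference 0.15 in sham and 1.46 in injury pairs).

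Rat 72 h calls might follow the pattern of the 24 h arrays, whose control probe sets were high, or an injury response. In sham 24 h minus naive, the 27 falls had a median of −0.67 (−1.64 at 72 h) and the 86 rises 0.91 (2.20 at 72 h), both between the written bounds and undecided. Over 4091 genes the 72 h change had r = 0.481 with sham 24 h minus naive. Of the rises tested in mouse, 87.7% (50 of 57) had the same sign there, as an injury response would predict, against 63.4% of all genes. Of the falls, 63.2% (12 of 19) did, which cannot tell.

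For rat 30 min, 16 of 100 splits called at least as many genes as the real 1 (highest other 214, with injury replicate 5 and sham replicate 3 in 1 group), so chance cannot be excluded for the count. It does not test Ccl3 itself, whose log2 signal was 9.08 to 9.76 in the 5 injury arrays and at most 7.45 in the 4 sham arrays. For rat sham against naive, 21 of 100 relabellings called at least the real 1 gene (highest other 1815), with the same reading; counts so far above the real ones point to a structure of the samples.

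Rat sham 4 h replicate 4 stood apart from its group in Emp1 (log2 signal 7.24), 1 of 45 gene tests (2.25 by chance). Array measures stood apart in 0 of 24 tests (1.2 by chance). In a group of 4 a pair of aberrant arrays hide each other, so this cannot judge sham 4 h replicates 3 and 4. Their log2 GAPDH signal was 11.0 and 10.1, against 12.1 to 14.7 in other rat arrays.

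The mouse injury effect differed between 72 h and 4 h in 332 genes, tested by that difference itself. Klk6 at least 6.24, Arg1 5.02, Lyz2 4.71, Itgam 4.61 and Cxcl2 −3.81 kept their calls with each array left out. Il1b −2.85 lost its call without injury 4 h 1 or 3 or sham 4 h 1b (adjusted p up to 0.122), and Ttc27 −2.47 without either sham 4 h array or sham 72 h 1d (up to 0.119). Adcy8 −2.52 lost it without any 1 array but injury 72 h 2 and sham 72 h 1c (up to 0.164). The rat effect differed in 193 genes, where Apobec1 at least 5.76 and Rasl11b −4.72 kept their calls. Adora1 4.62 lost its call without sham 72 h 2 (adjusted p = 0.0607), and Vom2r46 4.59 and Itpka −4.81 without either sham 72 h array or injury 72 h 2 or 3 (up to 0.121 and 0.0892). Pax4 4.62 and Nell2 −5.47 lost theirs also without any injury 4 h array or sham 4 h 3 or 4 (up to 0.168 and 0.169), and Nell1 −4.63 likewise except without injury 4 h 1 (up to 0.118).

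Control probe sets for antisense actin and GAPDH had a mean log2 level of 9.51 in rat injury and 9.11 in sham at 24 h, 9.18 and 7.40 at 8 h, 7.25 and 9.06 at 4 h, 8.33 and 8.24 at 30 min, 8.48 and 5.36 at 72 h, and 6.79 in naive rats. The injury 72 h arrays ranged from 6.61 (replicate 1) to 9.57. Those for ribosomal RNA had 10.55 and 9.999 at 24 h, 10.31 and 8.50 at 8 h, 8.45 and 10.02 at 4 h, 8.50 and 5.95 at 72 h, 8.37 and 8.79 at 21 d, and 7.95 in naive rats. The antisense covariate took rat 4, 8 and 72 h from 204, 29 and 113 to 28, 12 and 11 genes.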

How the results depend on the processing

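Alternatives were fixed before the data were examined, except those named above as chosen after seeing the data. Over the fits with no array left out singly, 84 summary values stayed within 1.5 times of the values in the report and 66 moved. For the moved and reversed values the cause was not tested, except that averaging or leaving out arrays leaves fewer samples and no filter tests more genes.

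For mouse 4, 8, 24 and 72 h, all uninjured arrays as 1 control group gave 443, 781, 1208 and 1504 genes, and averaged sham arrays 19, 191, 255 and 469. Only the compared groups gave 309, 296 and 475 at 8, 24 and 72 h, and the title letter as a block gave 551 at 72 h; that block could not be estimated for mouse 4 h, sham against naive or 72 h minus 4 h. Mouse sham against naive gave 4 genes after quantile normalization, 0 with no filter, 2 with the mean of probe sets and 0 with averaged sham arrays, and 72 h minus 4 h gave 80 with averaged sham arrays.

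Rat 30 min gave 0 genes with only the compared groups, 3 with all uninjured arrays and 0 without the 4 arrays. Rat 4 h gave 99 with no filter, 0 with the letter block, 1 with only the compared groups, 48 with all uninjured arrays, 44 without the 4 arrays and 28 with the antisense covariate. Rat 8 h gave 19 (letter), 48 (compared groups), 79 (all uninjured), 73 (without the 4) and 12 (antisense). Rat 24 h gave 24 (quantile), 462 (all uninjured) and 34 (without the 4). Rat 72 h gave 62 (quantile), 19 (compared groups), 239 (all uninjured), 376 (without the 4) and 11 (antisense). Rat sham against naive gave 0 (quantile), 0 (letter), 2 (without the 4) and 0 (antisense). Rat 72 h minus 4 h gave 117 (quantile), 0 (letter), 89 (without the 4) and 3 (antisense).

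Rat replicate numbers are shared between injury and sham, but pairs with the same number correlated at −0.41 to 0.36, over 0.1 in 4 of 15 pairs, so they only share a number. With replicate number as a block, rat 30 min gave 0 genes and sham against naive 2, other counts stayed within 1.5 times (147, 40, 15, 129 and 149 at 4, 8, 24 and 72 h and for 72 h minus 4 h), and 51 of 57 list calls were kept.

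Of 53 mouse list calls 25 were kept with an estimated correlation, and of 57 rat list calls 10, with 27 called by fry and 16 with an estimated correlation and without the 4 arrays. Spearman's rho between species was 0.137 with no filter, 0.174 with all uninjured arrays, 0.411 over called genes and 0.186 without the 4 arrays at 4 h. It was 0.232 (quantile), 0.167 (no filter), 0.282 (all uninjured) and 0.589 (called genes) at 8 h, 0.191 (no filter) and 0.540 (called genes) at 24 h, and 0.289 (no filter), 0.430 (all uninjured) and 0.613 (called genes) at 72 h. Reversed were Mcm5 at mouse 24 h (−0.22 with the mean of probe sets), Apoe at rat 72 h (0.13 after quantile normalization) and Nell1 in rat 72 h minus 4 h (0.17 with the antisense covariate). The rat 4 h neuronal list also reversed without the 4 arrays (to lower, adjusted p = 0.888).

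With 1 array left out at a time, mouse counts ranged from 18 to 43 at 4 h, 194 to 453 at 8 h, 249 to 769 at 24 h, 491 to 1294 at 72 h, 0 to 19 for sham against naive and 176 to 772 for 72 h minus 4 h. Rat counts ranged from 0 to 2 at 30 min, 19 to 1133 at 4 h, 10 to 20 at 8 h, 5 to 20 at 24 h, 18 to 326 at 72 h, 0 to 2 for sham against naive and 13 to 672 for 72 h minus 4 h, and stayed at 0 at 21 d. List calls ranged from 51 to 57 in mouse and 52 to 60 in rat. Species rho ranged from 0.0866 to 0.132 at 4 h, 0.161 to 0.231 at 8 h, 0.229 to 0.294 at 24 h and 0.309 to 0.376 at 72 h.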

Other observations

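Several probe sets measured the gene in 100 named results, and in 19 of them some probe set had the opposite sign, none of these with a raw p past the threshold. Over the named genes called in mouse, 10 of 27 at 4 h, 33 of 70 at 8 h, 47 of 75 at 24 h and 58 of 77 at 72 h kept their calls with each array left out in turn. In rat these were 9 of 43 at 4 h, 3 of 22 at 8 h, 4 of 10 at 24 h and 8 of 38 at 72 h. For 72 h minus 4 h these were 5 of 8 in mouse and 2 of 8 in rat.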
